A study of Mus musculus with 13 samples.

How the data were processed

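RNA was measured by sequencing in mouse embryonic fibroblasts, from embryonic day E12.5 per the labels, in 9 immunoprecipitation (IP) libraries and 4 total RNA libraries. The IP libraries fall into 3 groups of 3, pulled down with IgG, anti-IMP1 or anti-IMP2. The total RNA libraries are IMP1 WT, IMP1 KO, IMP2 WT and IMP2 KO, 1 of each. Libraries were made with an Illumina TruSeq kit, per the labels' protocols. The deposited values were whole-number read counts per Ensembl gene, 1 file per library, with no normalization by the authors seen in the values. Reads were handled with STAR and HTSeq against the mouse build mm10, per the submitters' processing notes, which give no versions, settings or annotation release. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes were not separated, and reads shared by near-identical copies such as histone genes, ribosomal protein genes and their pseudogenes are uncertain.

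The 5 tally lines that close each file were kept apart from the 43629 genes. Gene IDs were matched to symbols for 42462 genes, and 32737 symbols were found in the RefSeq table of GRCm38.p6, which gave biotypes, chromosomes and positions. Gene counts came to between 11430002 and 21756430 per library. A floor of 3 counts, the upper limit that a count of 0 allows, was 0.1379 to 0.2625 CPM, and floors and intervals cover counting error only.

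The IP libraries were tested in R 4.3.3 with edgeR 4.0.16. All 9 entered 1 quasi-likelihood fit with TMM scaling and edgeR's default expression filter by group, with no covariate. The contrasts were IMP1 against IgG, IMP2 against IgG and IMP1 against IMP2, 2-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. The common biological coefficient of variation was 3.84%. TMM factors were 0.992 to 1.001 in IgG IP, 0.894 to 0.896 in IMP1 IP and 1.12 to 1.128 in IMP2 IP. Standard errors were taken as the log2 fold change divided by the square root of the quasi-likelihood F. Overlaps were set beside independent calls and beside 20 simulations in which all 9 libraries were drawn from the IgG means. An IMP1-preferring or IMP2-preferring client was a gene past the threshold above IgG and above the other protein.

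Gene lists, 33 in number and written from general knowledge, were tested with limma 3.58.1 by camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Lists with fewer than 5 tested members were given values only. Calls were repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes.

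The total RNA libraries have no replicates, so no test was made. Log2 ratios of TMM-scaled CPM used a prior count of 2, and genes with at least 10 CPM in at least 1 of the 4 libraries were counted when they differed at least 2-fold. Fold changes printed without a logarithm are ratios of CPM with exact 95% counting intervals, and those against 0 counts are lower bounds from the floor. A list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with at least 3 measured members were placed, and a percentile below 2.5 or above 97.5 was outside the central range. This describes the libraries and does not test the genotype.

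Named genes were chosen by rule. In each IP comparison they are the 10 highest and the 10 lowest log2 fold changes among genes past the threshold, with average log2 CPM of at least 3 and no overlap between the groups' libraries. In each knockout they are the 10 highest and the 10 lowest log2 ratios among genes with at least 10 CPM in 1 of its libraries. Predicted genes, pseudogenes and genes without a symbol were passed over. The rule also names the IMP family in every library, the reported IMP ligands, of which not every member is reported here, and the leading 2 to 4 members of each list discussed. Gm26917, Fetub, Ostn, Krt19 and Alas2, and Igfbp5 as an example from both knockouts, were chosen after their values were seen.

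The steps were tested on simulated data drawn from the real means and library sizes. For IMP1 against IgG, with 13930 genes in the step, edgeR recovered 44%, 80%, 94% and 100% of 50 genes each changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and called 8 of 13730 unchanged genes (4.79% of its calls). Camera gave an adjusted p of 4.33e-70 for a raised list, and called 0 of 20 unchanged lists of 30 genes. A list of 50 genes raised by 0.5 on the log2 scale came to percentile 100 of random lists, and an unchanged list to 61.1.

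Alternatives for the IP libraries were DESeq2 1.42.0 (its Wald test, or its size factors within edgeR), limma voom, upper quartile and total count scaling, no count filter, a filter of 10 CPM in 3 libraries, only the libraries compared, wild-type total RNA as background, a 2-fold minimum, the replicate number as a block, and each library left out in turn. For total RNA they were the other WT library or the mean of both as reference, other scalings, prior counts of 0.5 and 8, CPM minimums of 1 and 30, and folds of 1.5 and 4. Protein-coding genes only and autosomal genes only were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Reads were not realigned, and protein levels, binding sites and isoforms were not analysed here.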

Results

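The series measured RNA in mouse embryonic fibroblasts, primary connective tissue cells grown from embryos, to compare the RNA clients of a pair of related RNA-binding proteins. The proteins are IMP1 (gene Igf2bp1) and IMP2 (gene Igf2bp2), of the insulin-like growth factor 2 mRNA-binding protein family, which bind cytoplasmic mRNAs and act on their stability, localisation and translation. RNA immunoprecipitation (IP), in which an antibody pulls down a protein with the RNA attached to it, gave 3 libraries for IMP1, 3 for IMP2 and 3 for a control immunoglobulin (IgG), which measures the background. Total RNA was sequenced in 1 library each from IMP1 wild-type (WT), IMP1 knockout (KO), IMP2 WT and IMP2 KO cells. The labels give no genotype for the cells of the IP libraries and do not say whether the 3 libraries of a group came from separate cultures.

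The deposited values were raw read counts for 43629 genes in 13 libraries. Gene counts per library came to 14756745 in IMP1 WT, 11430002 in IMP1 KO, 17225308 in IMP2 WT and 16575386 in IMP2 KO total RNA. The IgG IP libraries held 13907917, 11840189 and 14548720 counts, the IMP1 IP libraries 18938144, 17704900 and 18057296, and the IMP2 IP libraries 15718705, 20170777 and 21756430. Values below are in CPM, a library's counts scaled to a common total. Within each IP group, log2 CPM of libraries correlated across genes with Pearson's r of 0.9965 to 0.9981, although genes are not independent replicates. IgG IP differed from the other libraries in composition. Reads outside annotated genes were 24.6% ± 0.503 (SD, n = 3) of the records in IgG IP, 7.56% ± 0.118 in IMP1 IP and 5.04% ± 0.296 in IMP2 IP, and 4.429% to 5.1% in total RNA. The gene Gm26917, which can collect reads of ribosomal RNA, took 10.34% to 11.26% of the counts in IgG IP. None of the 13 mitochondrially encoded protein genes had a count in any library.

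The mRNAs of the IMP proteins themselves were compared first, since each knockout should lower its own gene. Igf2bp1 (ENSMUSG00000013415; GRCm38.p6, chromosome 11, 95957163 to 96005944) had 3.21 CPM in IMP1 KO against 32.28 in IMP1 WT total RNA, from 38 and 476 counts, a ratio whose 95% counting interval ran from 7.22-fold to 14.4-fold lower. Igf2bp2 (ENSMUSG00000033581; chromosome 16, 22059009 to 22163299) had 28.2 CPM in IMP2 KO against 149 in IMP2 WT, from 461 and 2512 counts, which was 5.29-fold lower (95% counting interval 4.79 to 5.86). Reads of the targeted gene therefore remained in both knockouts, and the counts per gene do not show which part of the transcript they came from. Igf2bp1 had 16.25 CPM in IMP2 KO against 23.96 in IMP2 WT, and Igf2bp2 had 130 CPM in IMP1 KO against 168 in IMP1 WT. Igf2bp3 (ENSMUSG00000029814; chromosome 6, 49085218 to 49215469), the third family member, had 37.96 CPM in IMP1 KO against 30.85, and 13.68 in IMP2 KO against 29.47. In the IPs, each protein's own mRNA held a larger share in its IP than in IgG IP, and the other protein's mRNA a smaller one. Igf2bp1 was at 191.4 ± 3.26 CPM (SD, n = 3) in IMP1 IP, 154.4 ± 1.37 in IgG IP and 116.4 ± 4.16 in IMP2 IP, with a log2 fold change of 0.31 (SE 0.0372, adjusted p = 2.12e-07) for IMP1 and -0.41 (SE 0.0377, adjusted p = 2.32e-09) for IMP2. Igf2bp2 was at 113.6 ± 5.34 CPM in IMP2 IP, 92.19 ± 1.66 in IgG IP and 58.19 ± 5.45 in IMP1 IP, with log2 fold changes of 0.3 (SE 0.0523, adjusted p = 1.86e-05) for IMP2 and -0.67 (SE 0.0565, adjusted p = 9.02e-10) for IMP1. Igf2bp3 passed the threshold against IgG for neither protein (adjusted p = 0.719 for IMP1 and 0.0861 for IMP2).

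**Figure D1:**
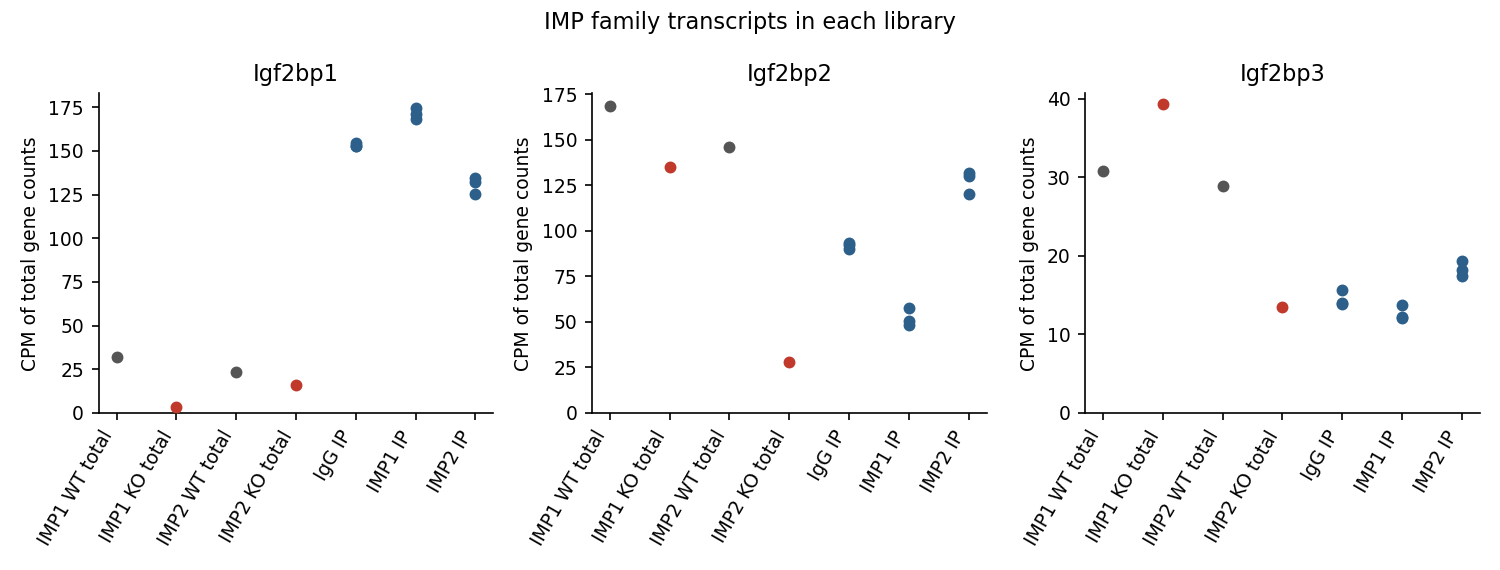
CPM of total gene counts of Igf2bp1, Igf2bp2 and Igf2bp3 (vertical axis) in every library, 1 point per library, grouped as IgG IP, IMP1 IP, IMP2 IP and the 4 total RNA libraries. Igf2bp1 is lowest in IMP1 KO among the total RNA libraries, Igf2bp2 is lowest in IMP2 KO, and in the IPs Igf2bp1 and Igf2bp2 are each highest in the IP of their own protein.

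The comparison of IMP1 IP with IgG IP asked which RNAs IMP1 recovers above background. By camera with its preset correlation, messages of extracellular matrix, adhesion receptors and endoplasmic reticulum chaperones were higher in IMP1 IP, and nuclear or abundant non-coding RNAs were lower. With an estimated correlation these list calls were lost (adjusted p = 0.0983, 0.218, 0.0506 and 0.0517), and transcript length was not tested. Nedd4, a ubiquitin ligase that acts on membrane receptors, had the second-highest rank and stood at 6571 ± 43.8 CPM (SD, n = 3) in IMP1 IP against 2203 ± 25.6 in IgG IP, a log2 fold change of 1.58 (SE 0.0289, adjusted p = 6.53e-21). Neat1, the nuclear RNA that scaffolds paraspeckles, was at 65.71 ± 1.14 CPM against 696.3 ± 6.47, a log2 fold change of -3.41 (SE 0.0364, adjusted p = 3.5e-25). Of the 14076 genes tested, 8948 passed the threshold, 4457 higher and 4491 lower, but 82 were at least 2-fold higher and 1740 at least 2-fold lower. Most differences were therefore small, with a median absolute log2 fold change of 0.5 among the genes past the threshold.

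The genes named as highest in IMP1 IP were led by Mir6236 (2.42 on the log2 scale) and Nedd4. The others were Selenop (1.57), Rpn1 (1.31), Pds5a (1.23), Lars2 (1.22), Selenos (1.2), Abca5 (1.19), Smpdl3b (1.18) and Txnrd3 (1.18). Selenop is a secreted selenium carrier, Selenos a selenoprotein of the endoplasmic reticulum and Txnrd3 a thioredoxin reductase with selenocysteine. Rpn1 is a subunit of the complex that attaches glycans to new proteins in the endoplasmic reticulum, Pds5a regulates cohesin, and Abca5 is a lipid transporter. Mir6236 and Lars2 can collect reads of ribosomal RNA and varied between libraries, with SDs of 13 and 21.6 CPM around means of 26.45 and 92.12 CPM in IMP1 IP. Besides Neat1, the named genes lowest in IMP1 IP were Kcnq1ot1 (-3.52), Xist (-2.6), Spaca6 (-2.54), Rbm4b (-2.16), Meg3 (-2.14), Malat1 (-2.04), Cplx2 (-1.91), Scarna2 (-1.81) and Iglon5 (-1.8). Kcnq1ot1, Xist and Meg3 are long non-coding RNAs of imprinting and X inactivation, Malat1 is an abundant RNA of nuclear speckles, and Scarna2 guides RNA modification in Cajal bodies. Of 538 long non-coding RNAs tested, 369 were lower and 7 higher in IMP1 IP.

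Among the gene lists, 38 of 43 extracellular matrix genes were higher in IMP1 IP and 3 lower, with a median log2 fold change of 0.57 (camera adjusted p = 9.54e-08; adjusted p = 0.0983 with an estimated correlation). They included the collagens Col5a2 (1.04) and Col1a2 (0.82), the matrix protein Postn (0.82) and the fibulin Fbln2 (0.81). Of 28 endoplasmic reticulum chaperones and processing factors, 25 were higher and 2 lower (median 0.43; adjusted p = 7.18e-07; adjusted p = 0.0506 with an estimated correlation), among them the glycoprotein quality sensor Uggt1 (0.95), Creld2 (0.86) and the chaperone Hspa5 (0.85). Cell cycle genes were higher in 29 of 44 cases and lower in 5 (median 0.26; adjusted p = 0.000229; adjusted p = 0.0517 with an estimated correlation), with Ccne1 (1.08), Top2a (0.94) and the replication helicase subunit Mcm6 (0.82) at the top. Integrins and adhesion receptors were higher for 19 of 32 and lower for 4 (median 0.28; adjusted p = 0.0027; adjusted p = 0.218 with an estimated correlation), with Itgav (0.9), Itga6 (0.82) and Itgb1 (0.79) leading. Proteasome subunits were higher for 20 of 31 and lower for 4 (median 0.27; adjusted p = 0.00518; adjusted p = 0.535 with an estimated correlation), including Psmd2 (1.02) and Psmb7 (0.95). Genes of IGF and insulin signalling were higher for 17 of 29 and lower for 3 (median 0.17; adjusted p = 0.00854; adjusted p = 0.307 with an estimated correlation), with the IGF2 receptor Igf2r (0.84) and the kinase Mtor (0.66) leading. Genes of TGF-beta and BMP signalling were higher for 17 of 30 and lower for 6 (median 0.27; adjusted p = 0.00857; adjusted p = 0.076 with an estimated correlation), including the receptor Tgfbr1 (0.78) and Ltbp1 (0.77).

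The lists lower in IMP1 IP were ribosomal proteins, Hox genes and nuclear or abundant non-coding RNAs. Of 79 cytosolic ribosomal protein genes, 43 were lower and 5 higher (median -0.34; adjusted p = 0.00122; adjusted p = 0.535 with an estimated correlation), although the lowest, Rps27 (-1.75), Rpl24 (-1.38) and Rps29 (-1.2), had about 1 CPM in IgG IP. Of 33 Hox genes, the transcription factors of body position, 21 were lower and 1 higher (median -0.62; adjusted p = 6.17e-05; adjusted p = 0.0517 with an estimated correlation), led by Hoxc5 (-1.96), Hoxa3 (-1.63) and Hoxd4 (-1.59). Of 15 nuclear or abundant non-coding RNAs, 12 were lower (median -0.99; adjusted p = 0.000229; adjusted p = 0.0517 with an estimated correlation). The counts adjusted over the list alone were the same for these 10 lists, except that 5 proteasome genes were lower. Lists not past the threshold were oxidative phosphorylation (13 higher and 27 lower of 74; 11 and 27 adjusted over the list alone; adjusted p = 0.258), mitochondrial ribosomal proteins (9 and 21 of 73; 9 and 20 adjusted over the list alone; adjusted p = 0.258), translation factors (15 and 6 of 32; 16 and 6 adjusted over the list alone; adjusted p = 0.125) and replication-dependent histones (16 and 10 of 46; 15 and 8 adjusted over the list alone; adjusted p = 0.362). Cholesterol synthesis (adjusted p = 0.0791), fibroblast markers (0.169), imprinted genes (0.258), glycolysis (0.726), p53 targets (0.811), Zfp zinc finger genes (0.849), actin and contractile genes (0.922) and interferon-stimulated genes (0.963) did not pass either.

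The comparison was tested with edgeR's quasi-likelihood fit, and 9803 genes (69.64%) had non-overlapping values in the IMP1 and IgG libraries, where chance gives 10%. The division into higher and lower genes depended on the scaling. The median of all genes moved by -0.17 (log2) with upper quartile scaling and by -0.153 with total count scaling, which put 31.6% and 33.33% of the genes past the threshold on the higher side against 49.81% as reported. The 10 lists past the threshold kept the sign of their medians under these scalings, but several shrank. With upper quartile scaling the medians were 0.00378 for IGF and insulin signalling, 0.0869 for cell cycle (21 higher and 12 lower), 0.0969 for the proteasome (15 and 8), 0.103 for TGF-beta and BMP signalling (15 and 8) and 0.11 for integrins (15 and 7).

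The comparison of IMP2 IP with IgG IP asked the same question for IMP2. By camera with its preset correlation, messages of oxidative phosphorylation, the proteasome and the actin cytoskeleton were higher in IMP2 IP, and histone messages and nuclear or abundant non-coding RNAs were lower. The non-coding RNAs also passed with an estimated correlation, and the others did not (adjusted p = 0.152, 0.137, 0.089 and 0.0823). Transcript length was not tested. Rpph1, the RNA of ribonuclease P, had the top rank at 3349 ± 975 CPM (SD, n = 3) against 655.7 ± 21 in IgG IP, a log2 fold change of 2.35 (SE 0.127, adjusted p = 2.59e-13). Ly6e, a lipid-anchored surface protein, was at 136.7 ± 1.68 CPM against 51.23 ± 1.78, a log2 fold change of 1.42 (SE 0.0433, adjusted p = 2.44e-17). Of 14076 genes, 10927 passed the threshold, 5674 higher and 5253 lower, of which 568 were at least 2-fold higher and 2298 at least 2-fold lower.

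The other genes named as highest in IMP2 IP, by log2 fold change, were Sh3bgrl3 (1.77), Tmem98 (1.64), Wdr83os (1.64), Timm17b (1.6), Msrb1 (1.6), Slc25a39 (1.47), Thy1 (1.46) and Ly6a (1.44). Timm17b is part of the translocase that imports proteins into mitochondria, Slc25a39 carries glutathione into mitochondria, Msrb1 is a selenoprotein that repairs oxidised methionine, and Thy1 and Ly6a are lipid-anchored surface proteins. The named genes lowest in IMP2 IP were Neat1 (-4.5), Kcnq1ot1 (-4.25), Xist (-3.75), Scarna2 (-3.62), Dleu2 (-2.8), Meg3 (-2.79), Spaca6 (-2.68), Rbm4 (-2.64), Malat1 (-2.61) and Rmrp (-2.55), the RNA of ribonuclease MRP. Malat1, the most abundant of them, was at 1042 ± 15 CPM in IMP2 IP against 6340 ± 74.9 in IgG IP (n = 3, adjusted p = 9.11e-25). Of the 538 long non-coding RNAs, 397 were lower and 21 higher.

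Nuclear-encoded genes of oxidative phosphorylation were higher in IMP2 IP for 65 of 74 and lower for 3, with a median log2 fold change of 0.82 (camera adjusted p = 2.83e-09; adjusted p = 0.152 with an estimated correlation). They included Uqcr10 of complex III (1.36), Sdhc of complex II (1.3), Atp5d of ATP synthase (1.26) and Cox6a1 of complex IV (1.26). Mitochondrial ribosomal proteins were higher for 68 of 73 and lower for 2 (median 0.78; adjusted p = 1.33e-09; adjusted p = 0.089 with an estimated correlation), led by Mrpl36 (1.17), Mrpl4 (1.13) and Mrpl34 (1.11). Proteasome subunits were higher for 30 of 31 (median 0.69; adjusted p = 1.68e-08; adjusted p = 0.137 with an estimated correlation), with Psmd8 (1.1), Psmb5 (1.07) and Psma6 (1.07) leading. Endoplasmic reticulum chaperones and processing factors were higher for 26 of 28 and lower for 1 (median 0.61; adjusted p = 1.24e-06; adjusted p = 0.0385 with an estimated correlation), including Ssr2 (1.1), Sdf2l1 (0.93) and Ddost (0.93). Translation factors were higher for 26 of 32 and lower for 5 (median 0.67; adjusted p = 0.000137; adjusted p = 0.152 with an estimated correlation), led by Eif5a (1.42), Eif3f (1.23) and Eif3h (0.92). Actin and contractile genes were higher for 23 of 31 and lower for 5 (median 0.66; adjusted p = 0.00163; adjusted p = 0.089 with an estimated correlation), with the filament-severing cofilin Cfl1 (1.35), profilin Pfn1 (1.22) and smooth muscle actin Acta2 (1.2). Cholesterol synthesis genes were higher for 16 of 22 and lower for 2 (median 0.49; adjusted p = 0.00445; adjusted p = 0.0823 with an estimated correlation), including Mvk (0.9), Ebp (0.86) and Msmo1 (0.85). Cell cycle genes were higher for 31 of 44 and lower for 11 (median 0.3; adjusted p = 0.0135; adjusted p = 0.089 with an estimated correlation), with Cdk4 (1.11), Ccne1 (0.8) and Ccnd3 (0.76) leading.

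Replication-dependent histones, whose messages lack a poly(A) tail, were lower in IMP2 IP for 43 of 46 and higher for 1 (median -1.07; adjusted p = 8.9e-08; adjusted p = 0.0823 with an estimated correlation), with Hist1h4c (-1.8) and Hist1h2ae (-1.63) the lowest. Of 15 nuclear or abundant non-coding RNAs, 14 were lower and Rpph1 was higher (median -2.54; adjusted p = 8.12e-06; adjusted p = 0.0385 with an estimated correlation). Zfp zinc finger genes were lower for 157 of 338 and higher for 47 (154 and 46 adjusted over the list alone; median -0.24; adjusted p = 0.000894; adjusted p = 0.089 with an estimated correlation), and their lowest members, Zfp750 (-5.03), Zfp783 (-3.11) and Zfp82 (-2.18), were below 3 CPM in IgG IP. The counts adjusted over the list alone were the same for the other 10 lists past the threshold. Extracellular matrix genes, which were higher in IMP1 IP, were lower for 27 of 43 and higher for 13 in IMP2 IP (median -0.3) and did not pass (adjusted p = 0.116; counts the same adjusted over the list alone). Ribosomal proteins had 42 higher and 23 lower of 79 (42 and 24 adjusted over the list alone), a median of 0.31 and a mean of -0.16, and did not pass (adjusted p = 0.26). Hox genes (adjusted p = 0.116), p53 targets (0.116), imprinted genes (0.27), glycolysis (0.27), TGF-beta and BMP signalling (0.367), fibroblast markers (0.419), integrins (0.638), IGF and insulin signalling (0.638) and interferon-stimulated genes (0.79) did not pass either.

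In edgeR's test, 11023 genes (78.31%) had non-overlapping values in the IMP2 and IgG libraries, where chance gives 10%. The median of all genes moved by -0.179 (log2) with upper quartile scaling and by 0.174 with total count scaling, which put 39.88% and 62.24% of the genes past the threshold on the higher side against 51.93% as reported. The 11 lists kept the sign of their medians under both. With total count scaling the Zfp list had 115 lower and 85 higher (median -0.06), and with upper quartile scaling the cell cycle list had 22 higher and 11 lower (median 0.12).

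**Figure D2:**
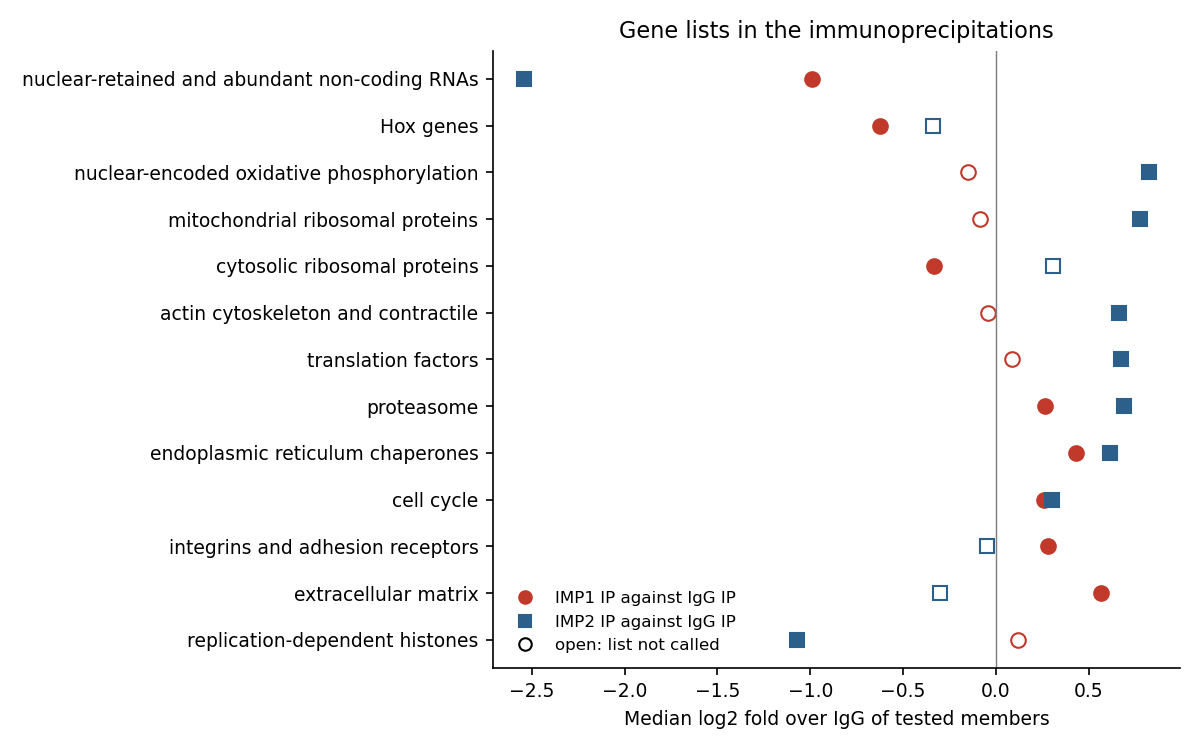
Median log2 fold change (horizontal axis) of 13 gene lists (vertical axis) in IMP1 IP over IgG and IMP2 IP over IgG, with filled points where camera's adjusted p was below 0.05. The lists of mitochondrial genes lie at 0.822 and 0.775 in IMP2 IP and near or below 0 in IMP1 IP, and the extracellular matrix list lies at 0.566 in IMP1 IP.

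The direct comparison of IMP1 IP with IMP2 IP asked which RNAs the proteins recover differently. By camera with its preset correlation, messages of oxidative phosphorylation, the mitochondrial and cytosolic ribosomes and the actin cytoskeleton were higher in IMP2 IP, and those of extracellular matrix and histones were higher in IMP1 IP. All these list calls were lost with an estimated correlation (adjusted p = 0.147 to adjusted p = 0.514 with an estimated correlation). Ahnak, a giant scaffold protein, was at 26830 ± 1010 CPM (SD, n = 3) in IMP1 IP, 6630 ± 366 in IMP2 IP and 20280 ± 257 in IgG IP, a log2 fold change of 2.02 between the proteins (SE 0.0378, adjusted p = 5.96e-21). Hmga1, a chromatin protein of proliferating cells, was at 22.27 ± 0.539 CPM in IMP1 IP and 99.42 ± 2.5 in IMP2 IP, a log2 fold change of -2.16 (SE 0.0505, adjusted p = 8.78e-20). Of 14076 genes, 10053 passed the threshold, 4800 higher in IMP1 IP and 5253 higher in IMP2 IP, of which 1363 and 1060 differed at least 2-fold.

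The other genes named as higher in IMP1 IP, by log2 fold change over IMP2 IP, were Rmrp (2.37), Hist1h1e (2.25), Mir6236 (2.25), Hist1h2bj (2.24), Hist1h2ak (2.18), Hist1h1d (2.11), Syne2 (1.94), Dync2h1 (1.93) and Zc3h11a (1.9). Syne2 and Dync2h1 encode very large proteins, a nuclear envelope anchor and a motor of cilia. Those higher in IMP2 IP were Ifitm2 (-2.21), Rpph1 (-2.18), Wdr83os (-2.16), Hspb6 (-2.03), Thy1 (-1.88), Pcbp2 (-1.86), Tagln2 (-1.85), Dazap2 (-1.81) and Timm17b (-1.79). Ifitm2 is a small membrane protein of antiviral defence, Hspb6 a small heat shock protein, Pcbp2 an RNA-binding protein and Tagln2 an actin-binding protein.

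Mitochondrial ribosomal proteins were higher in IMP2 IP for 66 of 73 and higher in IMP1 IP for 1 (median log2 IMP1 over IMP2 -0.83; camera adjusted p = 2.04e-11; adjusted p = 0.151 with an estimated correlation), led by Mrpl36 (-1.75) and Mrpl42 (-1.62). Oxidative phosphorylation genes were higher in IMP2 IP for 67 of 74 and in IMP1 IP for 5 (median -0.9; adjusted p = 2.35e-10; adjusted p = 0.233 with an estimated correlation), led by Cox8a (-1.68), Uqcr10 (-1.67) and Ndufb4 (-1.67). Histones were higher in IMP1 IP for 40 of 46 and in IMP2 IP for 1 (median 1.2; adjusted p = 7e-08; adjusted p = 0.147 with an estimated correlation). Extracellular matrix genes were higher in IMP1 IP for 31 of 43 and in IMP2 IP for 8 (median 0.82; adjusted p = 7.19e-05; adjusted p = 0.233 with an estimated correlation), with Col12a1 (1.72), the microfibril protein Fbn1 (1.61) and Col6a3 (1.53) leading. Integrins and adhesion receptors were higher in IMP1 IP for 21 of 32 and in IMP2 IP for 5 (median 0.38; adjusted p = 0.00654; adjusted p = 0.257 with an estimated correlation), led by the giant cadherins Fat1 (1.56) and Fat4 (1.45), but with total count scaling 11 were higher and 11 lower (median 0.05). Non-coding RNAs of the nucleus were higher in IMP1 IP for 13 of 15 and in IMP2 IP for 1 (median 0.66; adjusted p = 0.00172; adjusted p = 0.147 with an estimated correlation), including Mirg (2.32) and Rn7sk (1.76). Proteasome subunits were higher in IMP2 IP for 22 of 31 and in IMP1 IP for 4 (median -0.51; adjusted p = 0.00172; adjusted p = 0.322 with an estimated correlation), including Psmd11 (-1.39) and Psmb2 (-1.09).

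Ribosomal proteins were higher in IMP2 IP for 48 of 79 and in IMP1 IP for 18 (median -0.62, mean -0.22; adjusted p = 0.00654; adjusted p = 0.514 with an estimated correlation), including Rpl34 (-1.62), Rpl39 (-1.56) and Rplp1 (-1.53). Actin and contractile genes were higher in IMP2 IP for 22 of 31 (23 adjusted over the list alone) and in IMP1 IP for 8 (median -0.7; adjusted p = 0.00654; adjusted p = 0.233 with an estimated correlation), including Pfn1 (-1.64) and Cfl1 (-1.59). Translation factors were higher in IMP2 IP for 23 of 32 and in IMP1 IP for 8 (median -0.45; adjusted p = 0.00874; adjusted p = 0.317 with an estimated correlation), with Eif5a at -1.32 and the scaffold Eif4g1 at 1.11. Zfp zinc finger genes were higher in IMP1 IP for 144 of 338 and in IMP2 IP for 64 (139 and 62 adjusted over the list alone; median 0.15; adjusted p = 0.00996; adjusted p = 0.233 with an estimated correlation), including Zfp704 (1.66) and Zfp292 (1.42), but the median was -0.17 with total count scaling. The counts adjusted over the list alone were the same for the other 9 lists. Hox genes (adjusted p = 0.102), p53 targets (0.102), TGF-beta and BMP signalling (0.195), IGF and insulin signalling (0.224), cholesterol synthesis (0.229), endoplasmic reticulum chaperones (0.433), cell cycle (0.587), glycolysis (0.587), imprinted genes (0.764), fibroblast markers (0.867) and interferon-stimulated genes (0.88) did not pass.

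By edgeR, 10305 genes (73.21%) had non-overlapping values in the IMP1 and IMP2 libraries, where chance gives 10%. Total count scaling moved the median of all genes by -0.327 (log2) and put 27.82% of the genes past the threshold on the IMP1 side against 47.75% as reported. With an estimated correlation between genes, 0 lists passed camera in IMP1 IP against IgG, 2 in IMP2 IP against IgG and 0 in the direct comparison, with 6, 8 and 4 at an unadjusted p under 0.05 and 18, 22 and 21 by limma's fry. Lists with too few tested genes for a set test were covered by values only. Of their members, the epithelial keratin Krt19 was at 1.02 and 1.48 (log2 over IgG in IMP1 IP and IMP2 IP) and the erythroid enzyme Alas2 at -2.88 and -3.85, both below 5 CPM. Medians over IgG in IMP1 IP and IMP2 IP were 0.53 and -0.19 for 4 endothelial markers, -0.65 and 0.09 for 3 macrophage markers, -0.51 and -0.35 for 4 neural markers, -0.47 and 0.25 for 3 muscle markers and -0.35 and -0.15 for 3 cartilage markers.

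**Figure D3:**
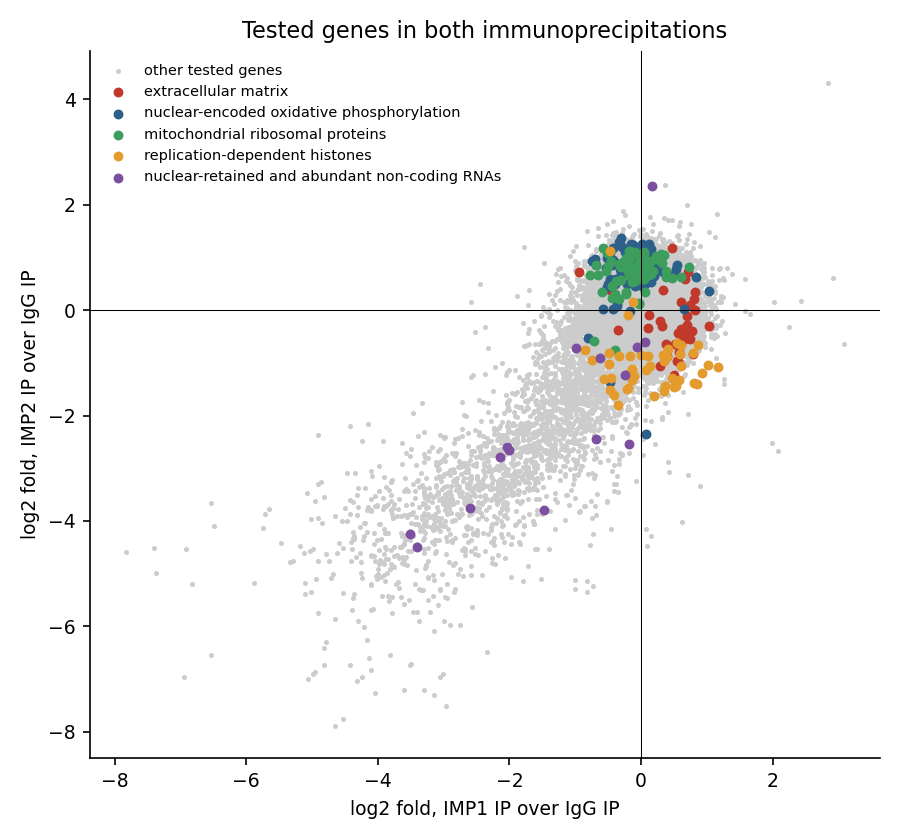
Log2 fold change over IgG of each of the 14076 tested genes in IMP1 IP (horizontal axis) and IMP2 IP (vertical axis), with genes of selected lists in colour. Mitochondrial genes lie above the others along the IMP2 axis with medians of 0.822 and 0.775, and the lower left quadrant holds the 2783 genes lower than IgG in both.

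The overlap of the clients was then counted. Enriched in both IPs over IgG were 2235 genes, where independent calls would give 1797, and lower than IgG in both were 2783, where independent calls would give 1676. At 2-fold, 3 genes were enriched in both (Fetub, Krt19 and Ostn, all below 2 CPM in every IP group), near the 3.31 given by independent calls, and 1531 were lower in both against 284.1. Genes enriched in IMP1 IP over IgG and higher than in IMP2 IP, called IMP1-preferring clients here, numbered 2758, and IMP2-preferring clients 4245. Of the 2235 shared genes, 624 were higher in IMP1 IP, 977 were higher in IMP2 IP and 634 passed in neither direction. On opposite sides of IgG lay 1380 genes enriched in IMP1 IP and lower in IMP2 IP, such as Pds5a (1.23 and -0.21) and Lamb2 (0.56 and -0.44). There were 1066 of the reverse kind, such as Pcbp2 (-0.96 and 0.9) and Hspb6 (-1.24 and 0.8). These counts became 706 and 2284 with total count scaling, where Pds5a stood at -0.0364 in IMP2 IP (adjusted p = 0.311), and 1375 and 1521 with upper quartile scaling. Both comparisons share the 3 IgG libraries, which alone makes their fold changes alike. In 20 simulations of unchanged groups against a shared control, the log2 fold changes correlated across genes with a mean r of 0.576, against 0.772 observed, and 68.5% of genes had the same sign, against 60.93% observed. Their covariance was 0.0161 in the simulations and 0.895 as observed. By edgeR, the simulations called 0 genes higher in both and at most 1 lower in both. At an unadjusted p under 0.05 their means were 81.2 higher and 78.9 lower in both, against 2368 and 2888 observed. No gene was enriched in the simulated groups, so they cannot show how much of the observed overlap comes from the shared control. With 3 IgG libraries the control could not be halved, so part of the overlap above independence can come from it. The shared count was 986 with upper quartile scaling and 1089 with a stricter count filter, and IMP1-preferring clients numbered 1523 with total count scaling. Against wild-type total RNA in place of IgG, 5926 genes were enriched in IMP1 IP and 5792 in IMP2 IP. Of the 4457 and 5674 genes enriched over IgG, 3138 and 2183 were also enriched over total RNA. Genes tested against both backgrounds numbered 12939 and 12770. Most genes enriched over IgG in IMP2 IP were therefore not called against total RNA. Overlaps under independent calls were not computed for this background, which also held Y-linked transcripts near 0 in the IPs.

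RNAs reported to bind IMP proteins, a list of 20 written from general knowledge before the data were examined, did not pass camera, which compares a list with the other genes. By limma's fry, which asks whether a list moves on balance one way, they were lower in IMP1 IP than IgG (adjusted p = 0.00275), higher in IMP2 IP than IgG (adjusted p = 1.09e-06) and higher in IMP2 IP than IMP1 IP (adjusted p = 3.82e-07). In IMP1 IP over IgG, 6 of 18 tested were higher and 7 lower (adjusted p = 0.811; the same adjusted over the list alone). In IMP2 IP, 10 were higher and 4 lower (adjusted p = 0.116; the same adjusted over the list alone). Directly compared, 4 were higher in IMP1 IP (5 adjusted over the list alone) and 9 in IMP2 IP (adjusted p = 0.224). Actb, the beta-actin message bound by IMP1 through its zipcode, was at 1657 ± 14.1 CPM in IMP1 IP, 1929 ± 26.3 in IgG IP and 3822 ± 74.4 in IMP2 IP, with log2 fold changes over IgG of -0.22 (adjusted p = 9.17e-07) and 0.99 (adjusted p = 1.52e-17). Myc, whose coding region IMP1 is known to protect, was higher in IMP1 IP (0.51, adjusted p = 1.06e-08) and stood at 0.02 in IMP2 IP (adjusted p = 0.698). Cd44, an adhesion receptor, was higher in both (0.25 and 0.44), as was the transcription factor Srf (0.36 and 0.34). Hmga1 and E2f1 were lower in IMP1 IP (-1.04 and -0.73) and higher in IMP2 IP (1.12 and 0.28), and Hmga2 was lower in both (-0.65 and -0.47). Igf2, the message that named the family, was near absent from the IPs at 0.45 ± 0.211 CPM in IgG IP, 0.18 ± 0.0984 in IMP1 IP and 0.78 ± 0.262 in IMP2 IP, with adjusted p = 0.0678 and 0.0858 against IgG, although wild-type total RNA held 1636 and 512.6 CPM. H19 was also low in the IPs, at 1.78 CPM or less, and Lin28b and Ucp1 were below the count filter.

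The comparison of IMP1 KO with IMP1 WT total RNA asked what changes when IMP1 is lost. With 1 library per genotype, no difference between these libraries can be tested, and every value below describes single libraries, with intervals for counting error only. The chemokine Cxcl14 had 1.01 CPM in IMP1 KO and 578.3 in WT (570.1-fold lower, 95% counting interval 326.2 to 1104). The bone matrix protein Spp1 had 25.95 and 11570 CPM (445.7-fold lower, 398.5 to 500.1). Igf2 had 37.19 CPM against 1636 (43.99-fold lower, 40.03 to 48.45). These folds became, against the other WT library, 1003 for Cxcl14 (573.8 to 1941) and 13.78 for Igf2 (12.52 to 15.2). The choice of WT library moved the fold of Igf2 by more than its counting interval shows, while the intervals of Cxcl14 overlapped. Of 10313 genes with at least 10 CPM in a total RNA library, 536 were at least 2-fold higher and 786 at least 2-fold lower in IMP1 KO (12.82%), whereas the WT libraries differed from each other at least 2-fold in 95 genes (0.9212%).

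The genes named as higher in IMP1 KO were Adamts18 (108.9-fold), Sost (1 count in WT; 241.8-fold, interval 42.9 to 9601), Fmo2 (113.9-fold), Kit (2 counts in WT; 120.3-fold, interval 32.85 to 1000), Cygb (84.77-fold), Rgs7bp (74.05-fold), Fbln7 (48.12-fold), Saa3 (50.82-fold), Rgs5 (45.35-fold) and Cd200 (49.08-fold). Sost encodes an inhibitor of Wnt signalling, Kit a growth factor receptor, Cygb a globin of fibroblasts, and Rgs5 a regulator of G-protein signalling typical of pericytes, at 1513 CPM against 33.36. Besides Cxcl14 and Spp1, the named lower genes were Ddx3y (at least 201.1-fold), Ppbp (at least 106.7-fold), Sim2 (at least 103.7-fold), Pitx1 (1 count in KO; 462.9-fold, interval 82.75 to 18310), Lhx9 (1 count in KO; 460.5-fold, interval 82.31 to 18220), Il1rl1 (189.3-fold), Eif2s3y (at least 90.65-fold) and Perp (215.2-fold). Pitx1 and Lhx9 are transcription factors of limb development. Ddx3y and Eif2s3y lie on the Y chromosome, and all 4 measured Y-linked genes were at least 2-fold lower in both knockouts. Those genes had between 133 and 1925 counts in the WT libraries and 3 or fewer in the knockouts. Each knockout therefore differed from its WT in Y-linked transcripts as well as in genotype. A difference in sex or origin between the cultures cannot be told apart from loss of the gene here. Genes of the autosomes alone gave 1244 at 2-fold. With the other WT library as reference, the named folds that moved by over 1.5 times were, besides that of Cxcl14, those of Cygb (32.31-fold), Kit (1 count in that library; 275.1-fold, interval 48.79 to 10920), Saa3 (23.52-fold), Ddx3y (at least 450.2-fold), Ppbp (at least 198.8-fold), Sim2 (at least 40.46-fold), Eif2s3y (at least 198.5-fold) and Perp (130.7-fold).

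Of the lists measured, 12 of 27 had medians outside the central 95% of 10000 expression-matched random lists in IMP1 KO, and 17 against the other WT library. Such positions also arose between the WT libraries (IMP1 WT over IMP2 WT). Ribosomal proteins, the proteasome and cell cycle stood there at percentile 100, extracellular matrix at 0 and integrins at 0.02. Glycolysis (5.935), endoplasmic reticulum chaperones (15.76) and p53 targets (14.92) were inside. An outside percentile alone therefore does not mark a knockout. Glycolysis was lowest among the pathways at a median log2 ratio of -0.99 (percentile 0), with 8 of 17 genes at least 2-fold lower and 0 higher, including the lactate exporter Slc16a3 (6.09 against 129 CPM), Eno1 (58.41 against 302.6), the glucose transporter Slc2a1 (44.97 against 175.6) and Pkm (531.5 against 1330). The reported IMP ligands had a median of -0.75 (percentile 0), with 6 of 15 at least 2-fold lower and 0 higher, among them Hmga1 (14.62 against 128.9 CPM), Cd44 (189.9 against 962.6), Hmga2 (103 against 511.9) and Myc (32.04 against 98.46). Hmga1 and Hmga2 were 8.815-fold and 4.972-fold lower, but 4.116-fold and 2.398-fold lower against the other WT library, where the list stood at -0.58. p53 targets stood at -0.49 (percentile 0.04; Cdkn1a 341.3 against 825.9 CPM, Btg2 31.87 against 162.5). Endoplasmic reticulum chaperones stood at -0.46 (percentile 0; Hspa5 986.9 against 1391 CPM). Ribosomal proteins stood at -0.26 (percentile 0.08), with Rpl34 at 3.55 against 118.2 CPM, but at -0.04 against the other WT library. Proteasome subunits stood at -0.23 (percentile 1.46), or -0.05 against the other WT library, and IGF and insulin signalling at -0.26 (percentile 1.02), with Igfbp5 at 8.54 against 337.8 CPM. Interferon-stimulated genes stood at 0.9 (percentile 100; Xaf1 20.96 against 1.9 CPM) but at 0.18 against the other WT library. TGF-beta and BMP signalling stood at 0.17 (percentile 99.54; Bmp4 827.3 against 76.15 CPM), Zfp zinc finger genes at 0.12 (percentile 99.95; Zfp608 28.32 against 9.97 CPM), of which 4 of 197 were at least 2-fold higher and 2 lower, and imprinted genes at 0.19 (percentile 98.75; Dlk1 322 against 149.1 CPM), although 7 of the 18 imprinted genes were at least 2-fold lower and 2 higher. Xaf1 went, against the other WT library, from 11.04-fold to 3.535-fold higher, Zfp608 from 2.841-fold to 1.664-fold and Dlk1 from 2.16-fold to 5.914-fold. Sex-linked transcripts stood at -6.86 (percentile 0), or -5.92 with genes at 0 counts set to their bound.

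The comparison of IMP2 KO with IMP2 WT total RNA asked the same for IMP2. Messages of cartilage matrix stood far above WT in IMP2 KO. Cnmd, a cartilage glycoprotein, had 4065 CPM against 1.96 (2077-fold, 95% counting interval 1479 to 3018). Col2a1, the main cartilage collagen, had 10570 CPM against 161.1 (65.6-fold, 63.16 to 68.16). The prostaglandin enzyme Ptgs2 had 6.72 CPM against 474.4 (70.6-fold lower, 58.49 to 86.01). Smooth muscle actin Acta2 had 734.8 CPM against 6207 (8.45-fold lower, 8.29 to 8.61). The folds became, against the other WT library, 1034 for Cnmd (799.5 to 1361), 31.01 for Col2a1 (30.15 to 31.9) and 113.1 for Ptgs2 (93.74 to 137.7). At least 2-fold higher were 772 genes and at least 2-fold lower 812 (15.36% of 10313), of which 1486 lay on autosomes.

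The other genes named as higher in IMP2 KO were Matn4 (443.5-fold), Scube2 (3 counts in WT; 468.3-fold, interval 159.9 to 2274), Cytl1 (321.7-fold), Col9a1 (252.9-fold), Matn1 (1 count in WT; 613.9-fold, interval 109.8 to 24290), Col26a1 (250.3-fold), Slpi (222.9-fold), Fzd9 (204.6-fold) and Col11a2 (182.4-fold). Matn1, Matn4, Col9a1 and Col11a2 are structural proteins of cartilage. Besides Ptgs2, the named lower genes were the Y-linked Ddx3y (3 counts in KO; 623-fold, interval 212.9 to 3024), Eif2s3y (2 counts in KO; 412.1-fold, interval 113.7 to 3409), Uty (at least 125.2-fold) and Kdm5d (at least 91.91-fold), the limb patterning gene Hoxd13 (at least 134-fold), Alkal1 (75.31-fold), Lrrc15 (75.19-fold), Kcnmb1 (1 count in KO; 190.3-fold, interval 33.76 to 7554) and the neuronal Stmn2 (57.35-fold). With the other WT library as reference, folds that moved by over 1.5 times were, besides those of Cnmd and Ptgs2, those of Cytl1 (633-fold), Col9a1 (161.6-fold), Matn1 (at least 179-fold), Col26a1 (1 count in that library; 1313-fold, interval 235.3 to 51910), Fzd9 (119.3-fold), Ddx3y (278.3-fold, interval 94.86 to 1352), Eif2s3y (188.2-fold, interval 51.69 to 1560), Uty (at least 49.22-fold), Kdm5d (at least 56.25-fold) and Hoxd13 (at least 64.39-fold). Sex-linked transcripts as a list stood at -7.53 (percentile 0), or -7.3 with genes at 0 counts set to their bound.

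In IMP2 KO, 21 of 27 lists had medians outside the central 95% of random lists, and 22 against the other WT library. Cartilage and bone markers stood at a median log2 ratio of 6.57 (percentile 100), with all 8 measured genes at least 2-fold higher, including Acan (247 against 1.66 CPM) and Sox9 (240.5 against 21.71), and the WT libraries expressed Col2a1 themselves. Macrophage and blood markers stood at 3.27 (percentile 99.54), with all 9 at least 2-fold higher, including Lyz2 (187.9 against 19.33 CPM) and Adgre1 (24.49 against 1.13). Fibroblast markers stood at 0.35 (percentile 99.79), with 3 of 12 at least 2-fold higher and 3 lower. Neural markers stood at -2.25 (percentile 0.09), with 2 of 3 at least 2-fold lower and 0 higher. Glycolysis was low again at -1.33 (percentile 0), with 13 of 17 genes at least 2-fold lower and 0 higher, among them Slc16a3 (7.76 against 157 CPM), Slc2a1 (47.16 against 182.9) and Pkm (303 against 1267). Hox genes stood at -3.22 (percentile 0), with 15 of 21 at least 2-fold lower and 1 higher, such as Hoxc5 (0.855 against 18.86 CPM) and Hoxc8 (4.46 against 37.95). Actin and contractile genes stood at -0.62 (percentile 0.03; Actg2 7.7 against 343.2 CPM, Cnn1 43.55 against 560.3) and cell cycle genes at -0.41 (percentile 0.01; Ccne1 13.56 against 46.02 CPM). Cholesterol synthesis stood at -0.65 (percentile 0; Hsd17b7 23.76 against 68.14 CPM) and integrins at -0.47 (percentile 0.13; Itga7 5.38 against 90.08 CPM). p53 targets stood at -0.67 (percentile 0), the reported IMP ligands at -0.46 (percentile 1.97; Cd44 42.64 against 649 CPM) and proteasome subunits at -0.4 (percentile 0.245; Psmd8 132.2 against 402.2 CPM). Oxidative phosphorylation stood at -0.22 (percentile 1.39) and the IMP family at -1.1 (percentile 1.14). The family list has 3 members and includes the targeted Igf2bp2, so its low position is partly built in. Imprinted genes stood at 0.99 (percentile 100), with 8 of 18 at least 2-fold higher and 1 lower, including Dlk1 (2384 against 54.44 CPM), Mest (1728 against 152.5) and Peg3 (984.5 against 118.4). Acan went, against the other WT library, from 148.7-fold to 63.89-fold higher, Adgre1 from 21.74-fold to 13.89-fold, Dlk1 from 43.79-fold to 15.99-fold and Mest from 11.33-fold to 17.17-fold, and Itga7 from 16.76-fold to 9.878-fold lower. Interferon-stimulated genes stood at 0.51 (percentile 98.1), or 1.48 against the other WT library, nuclear non-coding RNAs at 0.4 (percentile 99.41), Zfp zinc finger genes at 0.32 (percentile 100) and ribosomal proteins at 0.08 (percentile 97.82), which became -0.09 against the other WT library.

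Lists inside the central 95% in both knockouts, given as medians in IMP1 KO and IMP2 KO, were mitochondrial ribosomal proteins (-0.11 and -0.08), translation factors (-0.21 and -0.22) and extracellular matrix (-0.09 and -0.12). In IMP1 KO this also held for oxidative phosphorylation (-0.06), Hox genes (0.27, with 7 of 21 at least 2-fold lower and 3 higher), integrins (-0.22, with 9 of 31 lower and 2 higher), actin and contractile genes (-0.1), cell cycle (0.09), cholesterol synthesis (-0.09), the nuclear non-coding RNAs (0.13) and the IMP family (-0.37). It held there too for fibroblast markers (-0.02, and 0.03 with total count scaling), macrophage markers (-2.77, percentile 3.68, although 8 of 9 were at least 2-fold lower and 0 higher), neural markers (-0.41) and cartilage markers (-0.55, with 4 of 8 lower and 3 higher). In IMP2 KO it held for endoplasmic reticulum chaperones (-0.2), IGF and insulin signalling (-0.04) and TGF-beta and BMP signalling (0.02). Against the other WT library the sign changed in IMP1 KO for oxidative phosphorylation (0.04), mitochondrial ribosomal proteins (0.03), actin and contractile genes (0.07) and the nuclear non-coding RNAs (-0.02). It changed in IMP2 KO for extracellular matrix (0.22) and IGF and insulin signalling (0.02). Against that library 8 lists left the central 95% in IMP1 KO, namely cell cycle (0.398, percentile 100), Hox genes (0.56, percentile 99.97), actin and contractile genes (percentile 98.52), extracellular matrix (-0.365, percentile 0.02), integrins (-0.365, percentile 0.07) and fibroblast (-0.407, percentile 1.39), macrophage (-3.24, percentile 1.815) and neural markers (-1.12, percentile 0.735). Ribosomal proteins (percentile 49.4), interferon-stimulated genes (percentile 87.53) and the proteasome (percentile 42.46) came inside it, and cartilage markers stood at -0.00251. In IMP2 KO, mitochondrial ribosomal proteins (-0.251, percentile 0.06) and extracellular matrix (percentile 99.98) left it and ribosomal proteins (percentile 50.04) came inside, while fibroblast markers stood at 0.953. The WT libraries differed from each other by medians of 0.36 for cell cycle, -0.55 for interferon-stimulated genes and -0.31 for extracellular matrix (IMP1 WT over IMP2 WT).

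**Figure D4:**
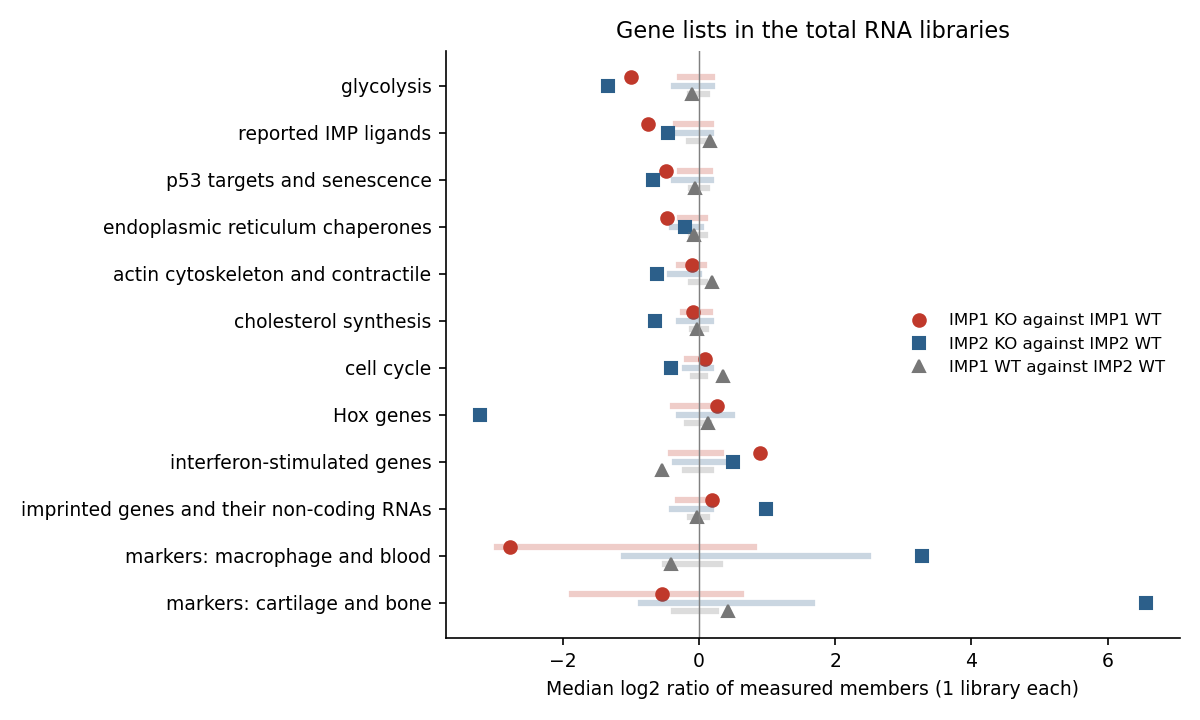
Median log2 ratio of the measured gene lists in IMP1 KO over IMP1 WT and IMP2 KO over IMP2 WT total RNA (1 library each), with pale bars for the central 95% of 10000 expression-matched random lists. Glycolysis lies below its bar in both knockouts (-0.991 and -1.33), and cartilage markers lie at 6.57 in IMP2 KO.

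The knockouts overlapped in part. At least 2-fold higher in both were 197 genes, where independence would give 40.12. Lower in both were 291, where independence would give 61.89, while 66 were higher in IMP1 KO and lower in IMP2 KO and 194 the reverse, where independence would give 42.2 and 58.84. Opposite differences were thus also more frequent than under independence. Igfbp5 was lower in IMP1 KO and higher in IMP2 KO, at 8.54 against 337.8 CPM in IMP1 KO and 7437 against 378.8 CPM in IMP2 KO. The log2 ratios correlated across genes with r = 0.21. The clients' median ratios in the knockouts were small. The 4104 measured genes enriched in IMP1 IP had a median log2 ratio of -0.03 in IMP1 KO (percentile 90.18 of random lists), and the 2486 IMP1-preferring clients 0.03 (percentile 100). In IMP2 KO these stood at -0.05 (percentile 51.45) and -0.000941 (percentile 100), so the position of IMP1-preferring clients among random lists was not particular to IMP1 KO. The 5267 genes enriched in IMP2 IP stood at -0.1 in IMP2 KO (percentile 0) and at -0.07 in IMP1 KO (percentile 0), and the 3954 IMP2-preferring clients at -0.09 and -0.08 (percentile 0 in both). The WT libraries also differed from each other, at 0.04 for genes enriched in IMP2 IP (percentile 100) and -0.06 for IMP1-preferring clients (percentile 0). Against the other WT library the percentiles in IMP1 KO became 22.12 for genes enriched in IMP2 IP, 84.92 for IMP2-preferring clients and 3.84 for IMP1-preferring clients. Against the other WT library the percentile of genes enriched in IMP1 IP became 0.02 in IMP1 KO and 99.4 in IMP2 KO. Across 9785 genes, the correlations between the knockout ratios and the IP fold changes lay between r = -0.0986 and 0.0779.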

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

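Chosen only after the result was seen were the tests of scaling and of carried-over IgG background for the mitochondrial mRNAs, the test of neural against other markers in IMP2 KO, changed more than once, and the test of the range over total RNA libraries for 13 transcripts near 0 in the IPs.

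Messages of oxidative phosphorylation and the mitochondrial ribosome, which are made in the nucleus and translated for import, were higher over IgG in IMP2 IP than in IMP1 IP, a difference lost with an estimated correlation (adjusted p = 0.233 and 0.151 with an estimated correlation, and 0.152 and 0.089 for IMP2 IP over IgG). A short gene span as the whole cause is argued against. The 146 members with a known span had a median log2 fold change of 0.8 in IMP2 IP, at percentile 100 of span-matched random lists (bounds 0.1 and 0.39, all genes at 0.04). With other scalings, the lowest list median in IMP2 IP over IgG was 0.596 and the highest for IMP1 IP over IMP2 IP was -0.764. Those scalings moved the median of all genes by -0.179 to 0.174 (log2) and by -0.327 to 0.0541. The shifts were smaller than the list medians and could not turn their sign, so this test did not decide on scaling. It shows only that the list medians exceeded the differences between these scalings. More IgG-type background in the IMP1 libraries stays open, since with total count scaling 46.04% of the 139 members higher in IMP2 IP (64) were lower in IMP1 IP than in IgG, but so were 43.85% of all 14076 genes, above the bound set for the test, which therefore decided nothing. Stronger recovery of these messages by IMP2 was not tested and stays open too, as do mature transcript length, other antibody-dependent losses and the unstated genotype of the IP cells.

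In the IMP2 KO library, cartilage and macrophage markers were higher than in IMP2 WT. A lower share of fibroblasts that raises every other cell type alike is argued against, because the highest log2 ratio of the 3 neural markers was 0.64 (Map2, with Stmn2 at -5.65), below the lowest of the 17 cartilage and macrophage markers, 1.31 (Runx2). Cartilage cells in the culture are a candidate source, since 10 of 14 cartilage genes outside the fixed lists, chosen after the pattern was seen but before their own values were, reached 10 CPM and were at least 2-fold higher, with Comp at 139.6 against 64.7 CPM and Hapln1 at 136.7 against 9.73. Snorc, Chad, Sox5 and Mia did not, while Comp, Papss2, Pth1r and Sox5 were above 10 CPM in IMP2 WT already, and an earlier test on the 8 fixed markers was set aside because they define the pattern. A lower share of fibroblasts, an effect of losing IMP2 on the fibroblasts' own programme and a difference between cultures stay open, with 1 library per genotype.

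Transcripts abundant in wild-type total RNA were near 0 in all 9 IP libraries, and after this was seen they were divided into Y-linked genes (Ddx3y at 50.99 and 114.2 CPM in the WT libraries and at most 2 counts in any IP library) and 13 other genes among 1850. Loss during preparation is argued against for the Y-linked genes, whose X-linked homologues had a median ratio of 2.46 between IP libraries and wild-type total RNA (Ddx3x 2.1, Kdm5c 2.82, Kdm6a 3.26, Eif2s3x 1.27). For the 13 others, which include Igf2, Cxcl14, Loxl2 and Igfbp2, other cells in the IPs than in the WT libraries may be the reason, since 61.54% of them (8) varied at least 4-fold over the 4 total RNA libraries, against an upper bound of 30.77% for random lists of like abundance. Xist, at 726.4 CPM in IgG IP and at most 10.24 CPM in total RNA, and the Y-linked genes, at 3 counts or fewer in both knockouts, also differed between the libraries. Preparation loss was not tested for the 13 genes, and the labels give no sex or genotype for the IP cells.

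The proteins' IPs differed by camera's direct test in 11 lists. The median log2 IMP1 IP over IMP2 IP was -0.62 for ribosomal proteins, -0.45 for translation factors, -0.903 for oxidative phosphorylation, -0.83 for mitochondrial ribosomal proteins, -0.703 for actin and contractile genes and -0.51 for the proteasome. It was 0.82 for extracellular matrix, 0.38 for integrins, 1.2 for histones, 0.66 for nuclear non-coding RNAs and 0.15 for Zfp zinc finger genes. Total count scaling moved the median of all genes by -0.327, toward IMP2 IP. With it the medians on the IMP1 side became, in the same order, 0.491, 0.0516, 0.874, 0.329 and -0.174. All 11 calls used the preset correlation and were lost with an estimated correlation (adjusted p = 0.147 to 0.514). For them transcript length was not tested.

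Genes named in the IP comparisons also lay on opposite sides of IgG. Higher in IMP1 IP, by log2 fold change over IMP2 IP, were Abca5 (1.48), Ahnak (2.02), Dync2h1 (1.93), Hist1h1d (2.11), Hist1h1e (2.25), Hist1h2ak (2.18), Hist1h2bj (2.24), Igf2bp1 (0.72), Lamb2 (0.99), Pds5a (1.44), Syne2 (1.94) and Zc3h11a (1.9), and among the list examples Col12a1 (1.72), Col5a2 (1.34), Col6a3 (1.53), Eif4g1 (1.11), Fat1 (1.56), Fat4 (1.45), Fbn1 (1.61), Igf2r (1.55), Itgav (1.06), Itgb1 (0.9006), Ltbp1 (1.1), Mtor (1.21), Top2a (1.36), Uggt1 (1.23), Zfp292 (1.42) and Zfp704 (1.66). Higher in IMP2 IP were Actb (-1.21), Dazap2 (-1.81), E2f1 (-1.004), Hmga1 (-2.16), Hspb6 (-2.03), Ifitm2 (-2.21), Igf2bp2 (-0.97), Ly6e (-1.78), Pabpc1 (-0.87), Pcbp2 (-1.86), Slc25a39 (-1.76), Tagln2 (-1.85), Thy1 (-1.88) and Wdr83os (-2.16), and among the list examples Atp5d (-1.58), Cfl1 (-1.59), Cox8a (-1.68), Mrpl36 (-1.75), Mrpl42 (-1.62), Mvk (-1.3), Pfn1 (-1.64), Psmb2 (-1.09), Psmd11 (-1.39), Rpl34 (-1.62), Rpl39 (-1.56), Rplp1 (-1.53), Sdhc (-1.63) and Uqcr10 (-1.67). Of these 56 genes, 52 were also past the threshold on opposite sides with total count scaling, where Itgb1 (0.641 and 0.0673), Itgav (0.743 and 0.00614) and Fat4 (-0.028 and -1.15) lay on the same side in IMP1 IP and IMP2 IP, and Pds5a stood at -0.0364 in IMP2 IP (adjusted p = 0.311). With upper quartile scaling Fat4 (-0.0452 and -1.5) lay on the same side and E2f1 stood at 0.1 in IMP2 IP (adjusted p = 0.12), and with protein-coding genes only Fat4 stood at 0.0673 in IMP1 IP (adjusted p = 0.119). All 56 kept opposite sides with DESeq2 size factors.

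Between the knockouts, some values had opposite signs, and the difference was not tested. Log2 ratios in IMP1 KO and IMP2 KO were -3.12 and 7.82 for Col9a1, -1.72 and 7.46 for Fzd9, 5.51 and -3.05 for Saa3, at most -6.7 and 3.2 for Sim2, and -1.31 and 7.48 for Slpi. Among list examples they were -4.2 and 7.11 for Acan, 1.08 and -5.45 for Actg2, at most -2.8 and 4.29 for Adgre1, -1.09 and 6.03 for Col2a1, 1.66 and -3.05 for Hoxc8, -5.28 and 4.3 for Igfbp5, -1.09 and 3.5 for Mest, -1.5 and 3.06 for Peg3, and -2.91 and 3.46 for Sox9. Sim2 and Adgre1 had 0 counts in IMP1 KO, so their values there are bounds from a floor of 3 counts in that library. Others rested on few counts, with 95% counting intervals in log2 of -9.74 to -1.78 for Col9a1, -10.8 to -2.98 for Acan and -7.79 to 0.776 for Slpi (1 count each in IMP1 KO), -4.08 to -0.507 for Fzd9 (4 counts in IMP1 KO) and -6.1 to -2.12 for Saa3 (3 counts in IMP2 KO). The interval of Slpi includes 0, so its opposite sign is not established. Against the other WT library Col2a1 was 1.003-fold lower in IMP1 KO (interval 0.9454 to 1.064), so its opposite sign rests on the choice of WT library. The median of ribosomal proteins was -0.26 in IMP1 KO and 0.0776 in IMP2 KO, or -0.0386 and -0.0887 against the other WT library. In the tally lines, which the comparisons did not use, records not uniquely aligned were 22.1% ± 0.928 in IMP1 IP and 27.49% ± 0.883 in IMP2 IP (SD, n = 3), above 17.28% ± 0.0503 in IgG IP and below the 38.43% to 40.88% of total RNA.

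The 6 libraries of each IP comparison allow 10 splits of 3 against 3, too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes. The real splits called 8948 genes for IMP1 against IgG, 10927 for IMP2 against IgG and 10053 for the direct comparison, and the highest of the others called 0 by edgeR and 0 by limma voom. At an unadjusted p under 0.05 by edgeR, the other splits gave 102 to 154, 31 to 140 and 115 to 242 genes.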

How the results depend on the processing

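Chosen after the data were seen were protein-coding genes only, for the IPs, and autosomal genes only, for the knockouts. The IP counts stayed within 1.5 times with DESeq2's test (7995 for IMP1 over IgG, 10111 for IMP2 over IgG, 9224 direct), limma voom (8832, 10867, 10060), no filter (10190, 13165, 10136), only the libraries compared (9318, 10439, 9569) and protein-coding genes (7541, 9157, 9185), which left out the histones for want of a biotype. Without 1 library they ranged from 8352 to 8623, 10536 to 11414 and 9580 to 10103, the overlap from 2072 to 2569, IMP1-preferring clients from 2600 to 2838, IMP2-preferring clients from 4032 to 4421, and list calls from 10 to 10, 11 to 12 and 11 to 11. Same-numbered libraries did not pair with IgG (r of -0.156 to 0.00203 for IMP1 and -0.309 to -0.13 for IMP2). Between IMP1 and IMP2, r was 0.456, 0.0298 and 0.413 for numbers 1, 2 and 3, against -0.46 to 0.232 for unlike numbers. Libraries 1 and 3 there correlated best with their own number and library 2 did not. The replicate block called 9017, 10961 and 10067 genes, of which 8894, 10880 and 9980 were the same genes as reported.

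The overlap of 2235 genes became 986 with upper quartile scaling, 1089 with 10 CPM in 3 libraries and 3 at 2-fold. IMP1-preferring clients became 1523 with total count scaling and 47 at 2-fold, and IMP2-preferring clients 379 at 2-fold. Fewer genes tested left 7240 calls for IMP2 over IgG with 10 CPM in 3 libraries, and the 2-fold minimum left 1822, 2866 and 2423 calls. Camera with an estimated correlation called 0, 2 and 0 of 23 lists (6, 8 and 4 at an unadjusted p under 0.05), and fry 18, 22 and 21. Reversed with upper quartile scaling were Ccnd1 in IMP1 over IgG (-0.106) and Btrc (-0.0242) and Myc (-0.156) in IMP2 over IgG. Also reversed were Btrc (-0.0177) and Myc (-0.15) with 10 CPM in 3 libraries, and Ccnd1 with total count scaling (-0.0889). Directly compared, Btrc (-0.304) and Srf (-0.301) were reversed with total count scaling. Over the named genes and settings, 47 results were lost, 28 gained, 8 reversed and 7 moved. Moved were Saa3 (4.484), Rgs5 (5.638) and Spp1 (-9.292) in IMP1 KO and Cnmd (9.965) and Ptgs2 (-6.793) in IMP2 KO against the other WT library, and Spp1 (-9.042) and Ptgs2 (-6.453) against the mean of both.

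For IMP1 KO and IMP2 KO, genes at 2-fold numbered 2711 and 2967 from 1 CPM, 807 and 1045 from 30 CPM, 2599 and 3111 at 1.5-fold, and 545 and 623 at 4-fold. They numbered 1250 and 1982 against the other WT library, and 1244 and 1486 on autosomes. Against the other WT library, client percentiles in IMP1 KO became 0.02 (IMP1-enriched), 22.12 (IMP2-enriched), 3.84 (IMP1-preferring) and 84.92 (IMP2-preferring), and 99.4 for IMP1-enriched in IMP2 KO. With clients at least 2-fold enriched, they became 82.48 (IMP1-preferring) and 5.605 (IMP2-preferring) in IMP1 KO, and 7.155 (IMP2-enriched), 37.6 (IMP1-preferring) and 3.35 (IMP2-preferring) in IMP2 KO. Beyond stricter thresholds, fewer genes and shorter lists, the cause was not tested. In the total RNA libraries, genes at 0 counts were limited to bounds by a floor per library of 0.1779 to 0.2536 CPM after TMM scaling.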

Other observations

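The test of selenoprotein genes was planned after 4 of them, Selenop, Selenos, Txnrd3 and Msrb1, had been named, and before the values of the others were seen, so no test here was chosen after its result. Selenoproteins carry selenocysteine, which is read from a stop codon through an element in the 3' untranslated region. Of the 14 tested selenoprotein genes not among those 4, 11 were higher in IMP1 IP than in IgG, and the median log2 fold change was 0.48 (camera p = 0.000131; p = 0.021 with an estimated correlation). Txnrd1 (1.04), Selenon (0.88), Gpx1 (0.81) and Selenoi (0.8) led, while Gpx4 (-0.06), Selenow (-0.02) and Selenom (0.32, adjusted p = 0.0594) did not pass. In IMP2 IP, 12 of the 14 were higher than in IgG and 0 lower, with a median of 0.73, and 8 were further above IgG than in IMP1 IP against 6 that were less so. There Selenow (1.41), Gpx1 (1.3) and Selenof (1.2) were further above IgG, while Txnrd1 (0.53), Selenoi (0.19), Txnrd2 (0.01), Selenoo (-0.17) and Selenot (0.16) were lower there than in IMP1 IP over IgG (0.62 for Txnrd2, 0.38 for Selenoo and 0.46 for Selenot). Selenoprotein messages may be recovered as a group in IMP1 IP, a hypothesis that binding data for the element would test, but the IMP2 IP values give no ground to call this specific to IMP1, and the difference between the IPs was not tested for this group.

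The transcripts near 0 in the IPs and abundant in both WT libraries were Igf2, Cxcl14, Loxl2, Igfbp2, Actg2, Acta1, Ndn, Aplp1, Creb3l1, C1qtnf3, Cthrc1, Adm and Gpx3, 0.703% of the genes with at least 100 CPM in both. Cxcl14 had 578.3 and 1017 CPM in IMP1 WT and IMP2 WT and 0 counts in all 9 IP libraries, and Loxl2 had 686.5 and 683.7 CPM against at most 0.647 CPM in an IP library. Xist was at 726.4 ± 22.8 CPM (SD, n = 3) in IgG IP, 107.9 ± 3.42 in IMP1 IP and 60.31 ± 10 in IMP2 IP, scaled by total gene counts, and at 4.41 in IMP1 WT, 0 in IMP2 WT, 10.24 in IMP1 KO and 7.42 in IMP2 KO.

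Libraries 2 and 3 of IMP2 IP were closer to each other (chi-square per degree of freedom 2.754) than to library 1 (7.702 and 8.074), and the other groups' pairs lay between 1.143 and 2.6.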
